A study of Vibrio natriegens with 4 samples.

How the data were processed

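RNA sequencing was run on 4 bacterial libraries labelled Vibrio natriegens CL-2, 2 grown without salt stress and 2 under 8% salt stress. Per the labels' protocols, total RNA was purified on silica spin columns, ribosomal RNA was depleted with a kit against bacterial 5S, 16S and 23S rRNA, and stranded libraries were made. The submitters' processing notes name Trim Galore, Bowtie2, featureCounts and DESeq2. Their versions, the settings, the genome build and the annotation are not given in the sources used here. Whether the counting used strand is not given either, so reads of overlapping or antisense genes cannot be assigned with certainty, and genes present as near-identical copies may share reads.

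The authors deposited 1 table of 4759 genes with 1 column per library, and its deposited values were on a log2 scale. Each value was the log2 of a normalized count plus 4, as read from the values themselves: the lowest value equalled the log2 of 4, and after that constant was removed 100% of the values in each library were whole multiples of 1 step, within 0.01 of a read. The steps matched the inverse of median-of-ratios size factors computed from the recovered reads, with a largest relative difference of 1.40e-09. The values used here are these back-transformed normalized counts. The recovered totals were 4602275 and 4437046 reads for the control libraries and 5826418 and 5105136 for the salt libraries.

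Gene names came from the table, which pairs each locus tag with a product and, for 1071 genes, a symbol. Of the 4759 locus tags, 0 matched the supplied table of 4690 V. natriegens genes, whose assembly is not that of the counted annotation. No coordinates are therefore given. Of the gene names, 0 contain tRNA, rRNA or the word ribosomal, so ribosomal proteins and tRNA ligases are not analysed here as groups. The symbol rpmG (FORC47_RS22425), that of a ribosomal protein, stands in the table without a product name, marked as a pseudogene, and is 1 of the 341 genes with a namesake length.

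The comparison was salt stress against no salt stress, with all 4 libraries in 1 fit. Genes with a normalized count of at least 10 in at least 2 libraries were kept, which left 4720 genes. The log2 of the normalized count plus 1 was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over the genes kept, and a gene was called changed at an adjusted p under 0.05. Fold changes are on this log2 scale with its pseudocount, which understates the change of low genes. Each fold is relative to the median gene, because the size factors behind the deposited values centre the median gene, whose fitted log2 fold change is close to 0. Errors are SDs over 2 libraries for levels and limma's standard errors (SE) for log2 fold changes. The labels number the libraries but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. An exact permutation of 2 against 2 libraries cannot give a p below 0.333.

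The design had assumed normalized counts on a linear scale, and the same limma fit was used after the back-transformation. Count models were planned on recovered reads, but edgeR and DESeq2 were not used here. Those tools were kept for values deposited as counts or on a linear scale. This was a rule set for the tests and not a limit of the recovered reads, which were fitted with limma-voom instead.

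Before the data were examined, 40 gene lists were fixed by symbols and product patterns. Of these, 32 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the residuals, few with 4 libraries, so it can hardly call a list. A further 8 lists were added after the gene names and values were seen and appear only among the closing observations. The genes named were fixed by rule: the 12 highest and 12 lowest log2 fold changes among called genes with a mean normalized count of at least 50 in 1 group, separated libraries and a symbol or informative product, every tested member of the osmolyte lists, and up to 4 members of each other list with the smallest p. Other genes named, mostly to show what a list held, were chosen after their values were seen.

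Alternatives covered the pseudocount (0.5 and 5, and 4 added after the data were seen), the filter, the scaling, the variance model, the replicate number as a block, leaving out each library in turn, the threshold, list membership by symbol, and limma-voom on the recovered reads, which was also added after the data were seen. The limma fit was tested on simulated data for 4720 genes with 200 lists of unchanged genes: of 50 genes simulated at each log2 fold change it called 76% at 0.5, 98% at 1 and 100% at 2 and 3, and called 2 of 4520 unchanged genes. Of the 200 random lists, 0 had a camera p under 0.05. The simulated genes varied independently, at a dispersion of 0.002, with the same spread of levels in both groups. In the data 4404 genes were called and the spread differed between groups. The simulation therefore checks the fit and does not show that the gene or list calls are reliable here. Closing tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Intervals on read ratios are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only, as does the floor of 3 reads per library for a gene at 0. Bootstrap intervals resample genes, which are not independent replicates, and do not cover the spread between libraries.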

Results

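The transcriptomes of libraries labelled Vibrio natriegens CL-2, a marine bacterium, were compared between 2 libraries without salt stress (controls) and 2 libraries at 8% salt stress. The series addressed how bacterial transcripts change under salt stress. The control libraries held 4602275 and 4437046 assigned reads and the salt libraries 5826418 and 5105136. The annotation counted was not that of V. natriegens in the supplied gene table: 0 of 4759 locus tags matched, and 161 gene names include spore or sporulation. Gene functions below therefore follow the names in the deposited table, not a V. natriegens annotation.

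Replicates were close, with a Pearson correlation of log2 values across genes of 0.997 between the controls and 0.998 between the salt libraries, against 0.717 to 0.725 between groups. Genes are not independent replicates, so no p is attached to these correlations. Replicates differed by more than counting noise (chi-square per degree of freedom 4.97 and 5.55), so neither pair was treated as a repeat deposit of 1 library. This excess does not show that they came from separate cultures. The groups differed in the spread of gene levels: the SD of log2 values across genes was 1.45 and 1.44 in the controls and 2.54 and 2.54 in the salt libraries. The control libraries had 4737 and 4736 genes with at least 10 reads and 0 genes without a read, whereas the salt libraries had 4598 and 4580 such genes and 31 genes at 0 each. The transfer-messenger RNA ssrA, which rescues stalled ribosomes, took 10.4% and 8.40% of control reads and 2.63% and 2.06% of salt reads.

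For 341 genes whose symbol also occurs in V. natriegens, the length of that namesake was at hand. Across these genes, control level followed namesake length with a Spearman correlation of 0.772 (95% bootstrap interval 0.715 to 0.820), and salt level with 0.361 (0.263 to 0.450). These are 7.17% of the genes in the table, under the 80% needed for a check of length on the comparison, so that check is void and the values describe these genes alone.

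**Figure D1:**
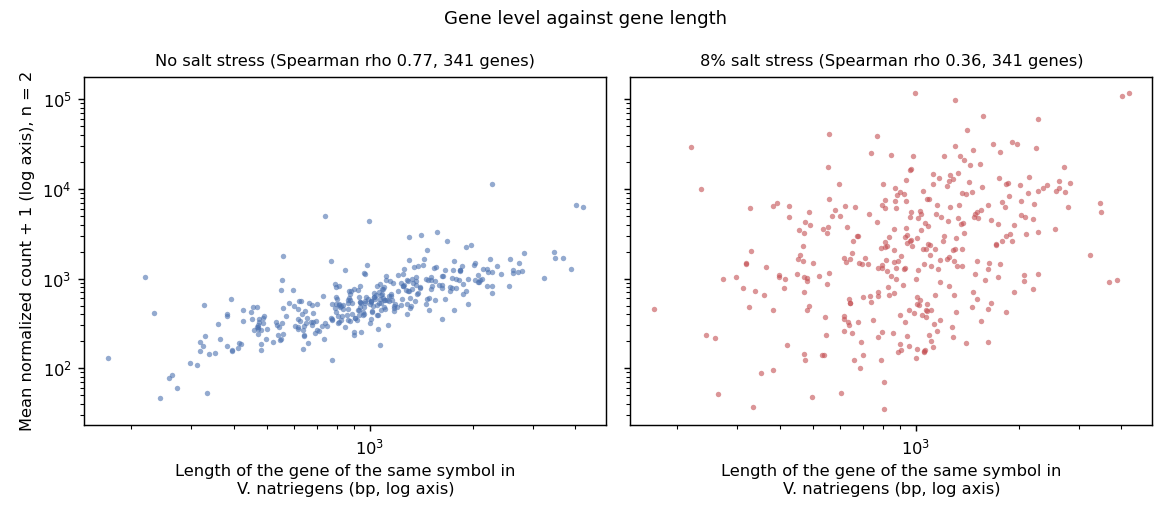
Mean normalized count plus 1 (log axis) of 341 genes against the length in base pairs (log axis) of the V. natriegens gene of the same symbol, in 2 control libraries (left) and 2 salt libraries (right). Each point is a gene; the Spearman correlation is 0.772 in the controls and 0.361 in the salt libraries.

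Under salt stress, genes of glycolysis, the tricarboxylic acid cycle, ATP synthase, translation factors, chaperones and DNA repair were higher relative to the median gene, and genes of branched-chain amino acid synthesis and the competence pilus were lower. These are calls of camera at a preset correlation: it called 12 lists, and 0 with an estimated correlation (adjusted p of 0.763 to 0.828). Estimated correlations were −0.050 for the pilus and −0.036 for the fermentation list, below the preset 0.01. Higher correlation therefore does not account for the loss of those lists. In the other called lists the estimates were above the preset value, from 0.022 for branched-chain synthesis to 0.767 for translation factors. Their calls thus rest on a correlation lower than the one estimated. The pilus list was also lost under several other settings. Median salt levels were 16274 normalized counts for glycolysis and 228 for branched-chain synthesis. Over all genes, the highest decile of salt level had medians of 7125 in salt and 888 in the controls. The lowest had 23.4 and 76.2, though ranking by salt level by itself widens the salt range. An even background in the controls, left open in the closing observations, is open for these lists too. Flagellar genes were also higher relative to the median gene, a distance that a scaling of whole libraries hardly alters by construction, but their own median was −0.07 with an equal total per library. Of 4720 genes tested with limma, 4404 changed at an adjusted p under 0.05, 2207 higher and 2197 lower. At least 2-fold changes were found for 1570 higher and 1356 lower genes, and changes of a log2 fold of at least 3 for 379 higher and 74 lower genes. The balance of directions depended on the scaling. With an equal total per library 830 genes were higher and 3693 lower (18.4% higher, against 50.1% with the deposited scaling), with an equal upper quartile 1477 and 3033 (32.7% higher), and with TMM 1987 and 2448 (44.8% higher). These scalings moved the median log2 fold change by −1.93, −0.98 and −0.27. Removing either control library left 4272 or 4243 changed genes; removing both would leave no comparison.

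**Figure D2:**
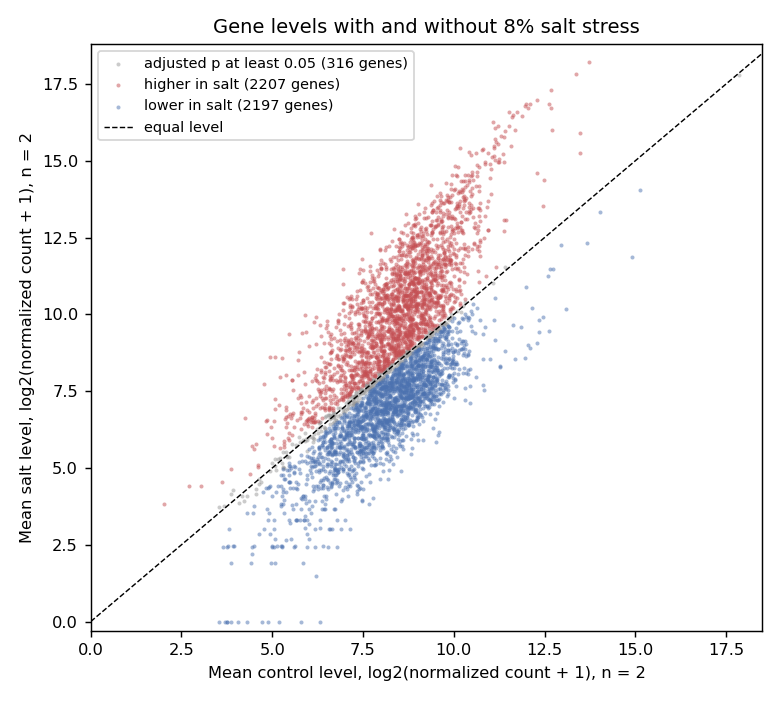
Mean level of each of 4720 tested genes in 2 salt libraries against 2 control libraries, both as log2 of the normalized count plus 1; red points are 2207 genes higher in salt, blue points 2197 genes lower and grey points 316 genes not passing limma's adjusted p of 0.05. The vertical spread exceeds the horizontal spread; with an equal total per library the split would be 830 higher and 3693 lower.

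Among the 12 genes with the highest log2 fold changes, raiA (FORC47_RS26710), which encodes a ribosome-associated translation inhibitor, rose from 1160 ± 121 to 43306 ± 6818 normalized counts (SD, n = 2; log2 fold change 5.22, SE 0.10, limma adjusted p = 3.39e-17). A ferritin-like protein gene (FORC47_RS05210) rose by 5.17, and eno, the enolase of glycolysis, by 5.06. A flagellin gene (FORC47_RS08600) rose by 4.93 and yqiS, a phosphate butyryltransferase, by 4.92. Adenylate kinase (FORC47_RS00790), which interconverts adenine nucleotides, rose by 4.92, the RNA polymerase alpha subunit rpoA by 4.88, bfmBAB of the branched-chain keto acid dehydrogenase by 4.88 and the phosphoglycerate mutase gpmI by 4.87. The set was completed by map (methionine aminopeptidase, 4.85), a WXG100 secretion target (FORC47_RS10450, 4.84) and leucine dehydrogenase (FORC47_RS21500, 4.82). SEs of these 12 genes lay between 0.06 and 0.10, and their control means between 209 and 4039 normalized counts, against a median of 332 over tested genes.

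The 12 lowest genes included several with spore-related names, and none had over 32 reads summed over both salt libraries. A GH25 lysozyme gene (FORC47_RS17545) had 193 reads in the controls and 0 in salt, at least 10.04-fold lower against a floor of 3 reads per library. moaD, of molybdopterin synthesis, had 262 and 2 reads, a ratio of salt to control of 0.0244 (95% interval 0.00293 to 0.0889). The YozD family gene FORC47_RS11260 had 204 and 3 reads, a ratio of 0.0469 (0.00960 to 0.139). An alpha/beta-type small acid-soluble spore protein gene (FORC47_RS09930), whose kind coats spore DNA, fell by 4.11 on the log2 scale, sasP of the same family fell by 3.95 and spoIIIAC, a stage III sporulation gene, by 3.74. The YjcZ sporulation gene FORC47_RS04950 fell by 3.88. A cupin gene (FORC47_RS15215) fell by 4.36, a sugar-binding regulator (FORC47_RS15205) by 3.84, the YqhV family gene FORC47_RS21660 by 3.75, a polysaccharide deacetylase gene (FORC47_RS09820) by 3.65 and a TusA family gene (FORC47_RS04155) by 3.61. Limma's adjusted p for these 12 genes was at most 5.01e-10, and their control means lay between 53.9 and 369.9 normalized counts.

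Uptake of compatible solutes, small molecules that balance external osmolarity, went both ways. Both genes of the glycine betaine transporter OpuD rose, FORC47_RS26990 from 1274 ± 10.7 to 8872 ± 560 normalized counts (SD, n = 2; log2 fold change 2.80, SE 0.06, limma adjusted p = 2.17e-16) and FORC47_RS02915 by 2.77. The sodium/proline symporter putP FORC47_RS18790 rose by 3.38, and its namesake putP FORC47_RS06355 by 0.96, a direction that turned to −0.03 with an equal upper quartile and −0.99 with an equal total per library. The 3 genes of a glycine betaine ABC transporter fell: the permease FORC47_RS14240 by 1.87, the ATP-binding subunit FORC47_RS14245 by 2.10 and the substrate-binding subunit FORC47_RS14250 fell by 2.66. Of the 7 listed members, 4 rose and 3 fell, with the same counts when adjusted over the list alone, and camera did not separate the list from other genes (adjusted p = 0.782). The list's median was 0.96, turning to −0.03 (3 higher, 3 lower) and −0.99 (3 higher, 4 lower) under those same scalings. The group's median control level was 875 normalized counts, against 332 for all tested genes. The lists for ectoine synthesis and betaine synthesis from choline had 0 members among the named genes.

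Ion transport genes also went both ways. Of 7 potassium uptake genes, 2 rose and 4 fell. A TrkA family gene (FORC47_RS20515) rose by 1.71 and a TrkH family gene (FORC47_RS06850) by 1.69, but with an equal total per library these were −0.23 and −0.26. Another TrkH gene (FORC47_RS06805) fell by 0.97 and kdpB, of the ATP-driven potassium pump, by 0.36. Of 13 sodium and proton antiport genes, which export cations in exchange for protons, 7 rose and 4 fell, against 6 and 6 with TMM, 4 and 9 with an equal upper quartile and 1 and 12 with an equal total per library. The cation:proton antiporter FORC47_RS08350 rose by 3.58 (SE 0.07), while FORC47_RS04360 fell by 1.78 and the regulatory subunit FORC47_RS26115 by 1.96. The Na+/H+ antiporter gene FORC47_RS21175 rose by 1.67, or stood at −0.28 with an equal total per library. Among 4 mechanosensitive channel genes, which release solutes when turgor is high, 2 rose and 2 fell. mscL rose by 2.44 and FORC47_RS28290 by 0.95, the latter turning to −0.04 with an equal upper quartile and −0.999 with an equal total. FORC47_RS11045 fell by 1.12 and FORC47_RS27495 by 0.41. Of 10 genes of proline and glutamate synthesis, 4 rose and 4 fell. The glutamine synthetase gene glnA rose by 3.90 and proC FORC47_RS01125, of the last step to proline, by 3.25. proI, named for that same step, fell by 2.14, as did a glutamate synthase family gene (FORC47_RS18800). These are the members with the smallest p, and the others are not described. None of these 4 lists passed camera, with adjusted p = 0.871, 0.782, 0.910 and 0.943 in this order, and their counts were the same when adjusted over the list alone. With an equal total per library the other 3 lists, of potassium, channels and proline, had 0, 1 and 2 genes higher against 7, 3 and 8 lower, and with an equal upper quartile 2, 1 and 2 higher against 5, 2 and 8 lower. Median control levels of the 4 lists were 657, 646, 323 and 520 normalized counts. The potassium and the proline lists had medians of −0.30 and −0.04 and means of 0.21 and 0.24, so median and mean differed in sign.

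**Figure D3:**
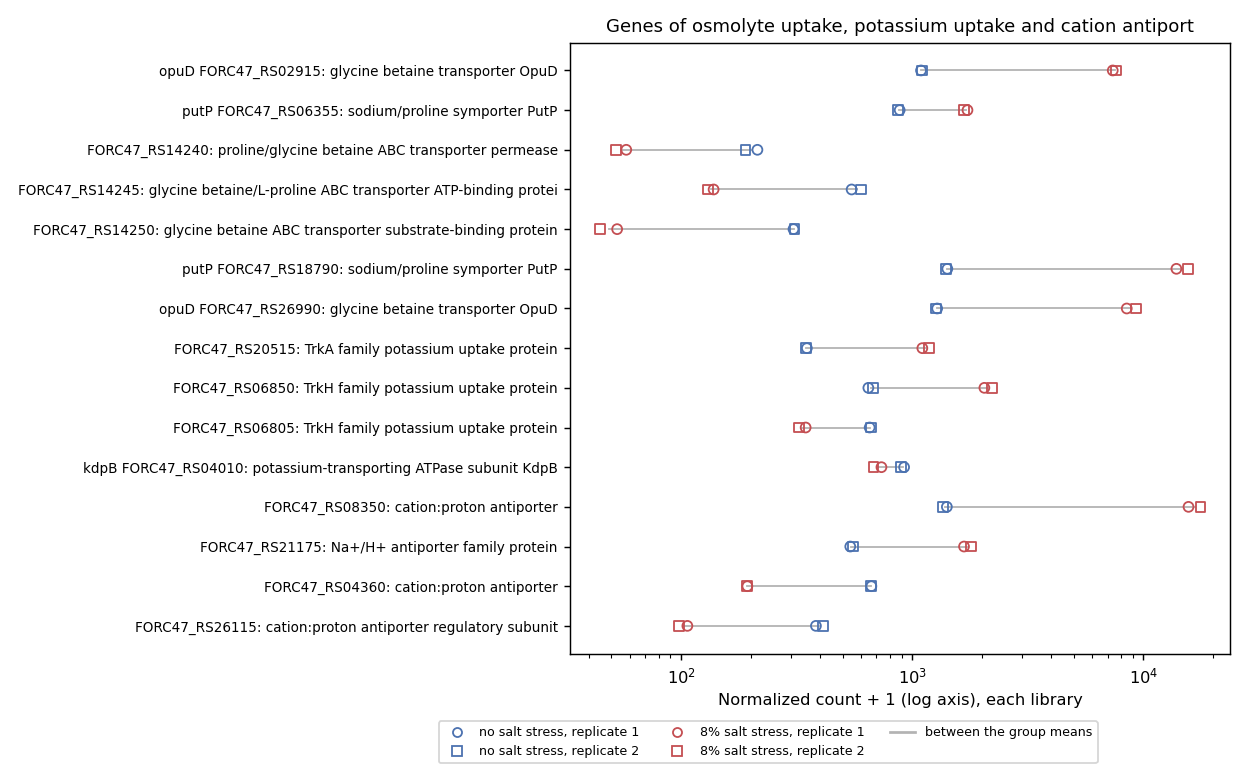
Normalized count plus 1 (log axis) in each of the 4 libraries for the 7 tested genes of compatible solute uptake and for 4 genes each of potassium uptake and of sodium and proton antiport; blue symbols are controls, red symbols salt libraries and grey lines join the group means. Both opuD genes and both putP genes lie to the right in salt and the 3 ABC transporter genes to the left; putP FORC47_RS06355 turns to −0.03 and −0.99 (log2 fold change) under equal upper quartile and equal total, and FORC47_RS20515, FORC47_RS06850 and FORC47_RS21175 turn negative under equal total.

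Protein folding and heat shock genes were higher as a group. Of 17 genes, 13 rose and 2 fell (median log2 fold change 3.28, camera adjusted p = 0.00357, adjusted p = 0.763 with an estimated correlation). The protease ATPase hslU rose from 983 ± 14.6 to 15118 ± 554 normalized counts (SD, n = 2; log2 fold change 3.94, SE 0.06, limma adjusted p = 6.95e-18), the DnaK exchange factor grpE by 3.90, clpX by 3.73 and the chaperonin gene groES by 3.64. Counts were 12 higher and 5 lower with an equal total per library (median 1.34). Of 14 general and osmotic stress regulators, 11 rose and 2 fell (median 2.58, camera adjusted p = 0.0320, adjusted p = 0.763 with an estimated correlation). The members with the smallest p encode cold-shock proteins, small RNA-binding proteins: cspD FORC47_RS25105 and cspB FORC47_RS08305 rose by 4.08, cspB FORC47_RS18160 by 4.07 and cspD FORC47_RS11780 by 3.43, and these namesakes may share reads. Among these regulators 7 were higher and 5 lower with an equal total per library (median 0.65). With members taken by symbol alone, camera did not call this list (adjusted p = 0.123). DNA repair and SOS genes rose in 12 of 15 cases and fell in 2 (median 2.26, camera adjusted p = 0.0104, adjusted p = 0.763 with an estimated correlation). recA, the strand-exchange recombinase, rose by 3.52, its target repressor lexA by 3.49, uvrA of excision repair by 2.58 and mutL of mismatch repair by 2.41. Repair genes split into 9 higher and 5 lower with an equal total per library (median 0.31). The 2 members that fell do other work, prli42 of the stressosome and a ceramidase domain gene (FORC47_RS04120), both named after their values were seen. Of 16 oxidative stress genes, 11 rose and 4 fell, which camera did not call (median 1.83, adjusted p = 0.0944), and with an equal total per library the median was −0.12, with 6 higher and 8 lower. Of the members with the smallest p, the superoxide dismutase sodA FORC47_RS22080 rose by 4.59, the peroxidase ahpC by 4.55, tpx by 3.79 and thioredoxin trxA by 3.61. Counts in these 4 lists were the same when adjusted over the list alone, and their median control levels were 748, 243, 825 and 507 normalized counts in this order. The envelope stress list had 2 members that do other work, rpoE (here the RNA polymerase delta subunit), which rose by 3.43, and spoIIGA, a sporulation peptidase, which fell by 2.90.

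Genes of glycolysis, the tricarboxylic acid cycle and ATP synthase were higher in salt under each scaling. Of 15 glycolysis genes, 14 rose and 1 fell (median log2 fold change 3.82, camera adjusted p = 0.000683, adjusted p = 0.763 with an estimated correlation). The triose-phosphate isomerase tpiA rose from 1555 ± 22.5 to 38880 ± 619 normalized counts (SD, n = 2; log2 fold change 4.64, SE 0.07, limma adjusted p = 5.93e-18). Phosphoglycerate kinase (FORC47_RS26430) rose by 4.50, fructose-bisphosphate aldolase (FORC47_RS27550) by 4.37 and the sugar phosphotransferase carrier ptsH by 4.09. Of 24 genes in the tricarboxylic acid cycle list, 18 rose and 5 fell (median 3.25, camera adjusted p = 0.00676, adjusted p = 0.828 with an estimated correlation). lpdA FORC47_RS20465, a dihydrolipoyl dehydrogenase, rose by 4.59, sdhB by 4.23, sdhC by 3.56 and the isocitrate dehydrogenase icd by 4.19. Product patterns also drew in leuA and leuB of leucine synthesis, which fell, and bshA of bacillithiol synthesis, all 3 named after their values were seen. Of 12 ATP synthase genes, 10 rose and 2 fell (median 3.54, camera adjusted p = 0.0132, adjusted p = 0.763 with an estimated correlation). atpA rose by 3.84, atpG by 3.81, atpE by 3.80 and atpC by 3.63. The fermentation and anaerobic respiration list had 18 of 20 genes higher and 2 lower (median 1.45, camera adjusted p = 0.00357, adjusted p = 0.763 with an estimated correlation), and with an equal total per library a median of −0.50, with 7 higher and 12 lower. Its leading genes make acetate and lactate: ackA rose by 3.40, pta by 3.03 and the L-lactate dehydrogenases FORC47_RS25175 and FORC47_RS09625 by 3.22 and 2.72. The list also drew in arcA, here an arginine deiminase, and cytochrome c oxidase genes of aerobic respiration such as coxB, both named after their values were seen. The glycolysis, tricarboxylic acid cycle and ATP synthase lists had 13, 15 and 8 genes higher against 1, 8 and 3 lower with an equal total per library. Counts in these lists were the same when adjusted over the list alone. Median control levels were 1426, 844, 355 and 637 normalized counts in this order.

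Storage and lipid lists did not pass camera. All 4 tested genes of polyhydroxybutyrate, a carbon storage polymer, rose (median 2.19, adjusted p = 0.0517): phaP by 3.43, phaR by 2.22, acetoacetyl-CoA reductase (FORC47_RS06835) by 2.16 and the synthase subunit phaC by 1.72, though phaC stood at −0.22 with an equal total per library. Of 28 genes of fatty acid and membrane lipid synthesis, 18 rose and 9 fell (median 2.24, adjusted p = 0.0859). The acyl carrier protein gene acpP rose by 4.59, accC by 4.12, fabI by 4.04 and fabG by 3.90. Of 16 fatty acid degradation genes, 11 rose and 3 fell (adjusted p = 0.199), among them enoyl-CoA hydratases FORC47_RS23285 (3.35) and FORC47_RS11450 (2.32), an acyl-CoA dehydrogenase (FORC47_RS15820, 2.49) and acetyl-CoA acetyltransferase (FORC47_RS25900, 2.24). That list's median of 0.62 turned to −0.36 with an equal upper quartile (6 higher, 9 lower) and −1.32 with an equal total (5 higher, 11 lower). Counts in the 3 lists were the same when adjusted over the list alone, with median control levels of 416, 436 and 713 normalized counts.

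Translation factor and cell wall genes were higher as groups relative to the median gene, but the cell wall median itself was −0.20 with an equal total per library. All 14 tested translation factor genes rose (median log2 fold change 3.79, camera adjusted p = 0.000302, adjusted p = 0.763 with an estimated correlation). The initiation factor gene infA rose from 1038 ± 18.9 to 29356 ± 9.32 normalized counts (SD, n = 2; log2 fold change 4.82, SE 0.06, limma adjusted p = 4.32e-18), infC by 4.16, the recycling factor frr by 4.04 and efp by 3.71. The list also held greA, a transcription elongation factor, and prmC, which methylates release factors, both named after their values were seen; with an equal total per library 11 genes were higher and 2 lower. Of 32 genes of peptidoglycan synthesis, 23 rose and 7 fell (median 1.75, camera adjusted p = 0.0132, adjusted p = 0.763 with an estimated correlation). With an equal total per library 11 were higher and 17 lower, and camera no longer called the list. The division gene ftsZ rose by 3.59, murA of the first committed step by 3.47, ftsA, annotated as a pseudogene, by 3.45 and murC by 3.24. Counts in both lists were the same when adjusted over the list alone, and their median control levels were 893 and 927 normalized counts. Among 5 stable RNAs, rnpB, the RNase P RNA, rose by 4.70, while ffs of the signal recognition particle fell by 0.70 and the 6S RNA genes ssrS FORC47_RS08160 and ssrS FORC47_RS08165 fell by 1.07 and 1.34. ssrA stood at −0.06 relative to the median gene (limma adjusted p = 0.822, gene chosen after its values were seen), although its share of reads was lower in salt. The list did not pass (camera adjusted p = 0.748), its median (−0.70) and mean (0.31) differed in sign, and its counts of 1 higher and 3 lower were the same when adjusted over the list alone. With an equal upper quartile and with an equal total per library, 1 was higher and 4 lower (medians −1.68 and −2.64).

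Competence pilus genes were lower under each scaling, and motility genes were higher relative to the median gene, but their own median was −0.07 with an equal total per library. Of 44 flagellar and chemotaxis genes, 38 rose and 5 fell (median log2 fold change 1.88, camera adjusted p = 8.13e-05, adjusted p = 0.763 with an estimated correlation), and with an equal total per library, 20 were higher and 21 lower. The flagellin gene FORC47_RS08600 rose from 209 ± 3.15 to 6413 ± 333 normalized counts (SD, n = 2), the hook-associated genes FORC47_RS08500 and flgK by 3.18 and 2.94 and a chemotaxis gene (FORC47_RS08585) by 2.63. The type III secretion list held only 2 flagellar export genes, FORC47_RS08630 (FliP) and FORC47_RS08645 (FlhB), which rose by 1.78 and 1.15 but stood at −0.16 and −0.79 with an equal total per library. All 7 members of the type IV pilus and biofilm list fell under each scaling (median −1.30, camera adjusted p = 0.0314, adjusted p = 0.763 with an estimated correlation). Camera lost the list without either salt library, with the replicate number as a block, with an equal total and with an equal upper quartile. All 7 stayed lower under both scalings, with medians of −3.24 and −2.28, where the median of all genes was −1.93 and −0.98. Of its members, 6 belong to the competence pilus, a DNA uptake structure, and calY, named after its values were seen, encodes a biofilm matrix protein: comGD fell by 1.57, comGA by 1.54, comGF by 1.40 and comGB by 1.30. Of 12 genes of quorum sensing and cyclic di-GMP, 4 rose and 8 fell (camera adjusted p = 0.453), or 3 and 9 with an equal upper quartile and 1 and 11 with an equal total per library. luxS, of autoinducer synthesis, rose by 2.47, while lsrB fell by 2.36, diguanylate cyclase FORC47_RS20615 by 2.11 and GGDEF gene FORC47_RS20860 by 1.92. Counts were the same when adjusted over each list alone. Median control levels were 397 for the flagellar, 238 for the pilus and 499 normalized counts for the quorum sensing list.

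**Figure D4:**
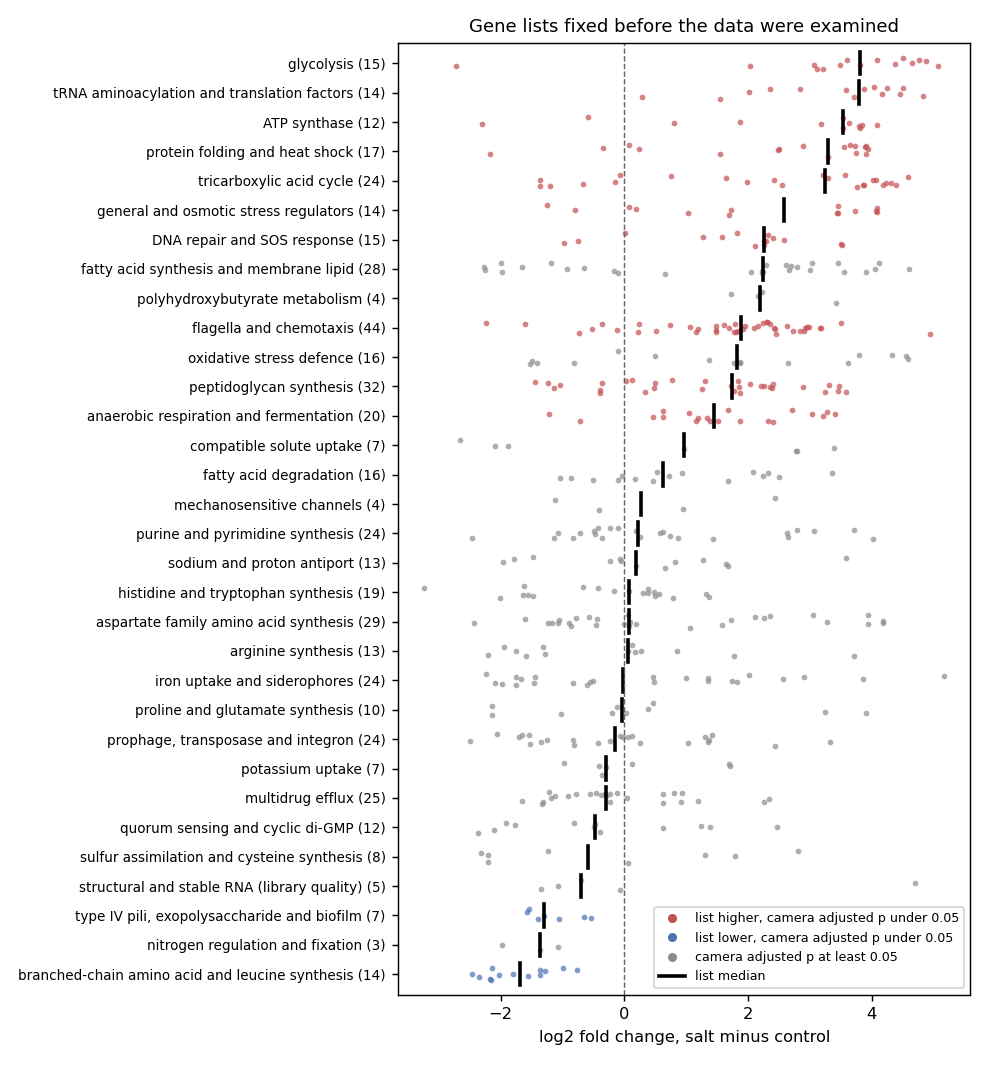
Log2 fold change (salt minus control) of each tested member of the 32 gene lists with at least 3 members, with member numbers in brackets; red and blue mark 10 lists higher and 2 lower by camera, grey 20 lists not passing, and black bars list medians. Of the 10 lists called higher, the flagellar, peptidoglycan and fermentation lists have negative medians (−0.07, −0.20 and −0.50) with an equal total per library. That scaling moves the median of all genes by −1.93 and also turns medians of lists not called, such as compatible solute uptake (−0.99) and oxidative stress (−0.12).

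Biosynthesis of branched-chain amino acids was lower. Of 14 genes, 13 fell and 1 rose under each scaling (median log2 fold change −1.68, camera adjusted p = 0.00184, adjusted p = 0.763 with an estimated correlation). The ketol-acid reductoisomerase gene ilvC dropped from 755 ± 26.6 to 147 ± 4.45 normalized counts (SD, n = 2; log2 fold change −2.35, SE 0.07, limma adjusted p = 5.64e-15), and ilvB and ilvE fell by 2.16 each. The exception, alsS, encodes an acetolactate synthase of acetoin production and rose by 2.13. Other synthesis lists did not pass camera, and all but the nitrogen list had members in both directions with the deposited scaling. Arginine synthesis (5 higher, 6 lower, adjusted p = 0.683) held the repressor gene argR, which rose by 3.71, and argB, argC and acetylornithine transaminase (FORC47_RS21310), which fell by 1.95, 1.75 and 1.28. The aspartate family (13 higher, 12 lower, adjusted p = 0.782) held asd and dapA, which rose by 4.19 each, dapG by 3.94 and LL-diaminopimelate aminotransferase (FORC47_RS14805) by 3.93. In histidine and tryptophan synthesis (9 higher, 9 lower, adjusted p = 0.757; 6 and 10 with TMM, 2 and 17 with an equal upper quartile, 0 and 19 with an equal total per library), trpA fell by 3.23, trpD by 2.00 and trpE by 1.47, while hisC rose by 1.36 but stood at −0.58 with an equal total per library. Purine and pyrimidine synthesis (13 higher, 10 lower, adjusted p = 0.722) held pyrH, guaB, adenylosuccinate synthase (FORC47_RS28240) and purB, which rose by 4.02, 3.71, 3.06 and 2.64. In sulfur assimilation (3 higher, 4 lower, adjusted p = 0.782), cysK rose by 2.80 and cysE by 1.79, the latter at −0.15 with an equal total per library, while sat and phosphoadenylyl-sulfate reductase (FORC47_RS07370) fell by 2.20 and 2.19. All 3 genes of the nitrogen list fell (adjusted p = 0.0944): nitrite reductase FORC47_RS07385 by 1.98, nitrate reductase FORC47_RS10390 by 1.36 while ammonium transporter FORC47_RS05940 fell by 1.08. With an equal total per library the arginine, aspartate, purine and sulfur lists had 1, 9, 6 and 1 genes higher against 12, 19, 18 and 7 lower, and with an equal upper quartile 2, 11, 7 and 3 higher against 11, 17, 16 and 5 lower. Medians of arginine (0.05) and of histidine and tryptophan synthesis (0.08) differed in sign from their means (−0.24 and −0.35). Counts were the same when adjusted over each list alone. Median control levels of these 7 lists, from branched-chain to nitrogen, were 771, 547, 521, 315, 596, 539 and 685 normalized counts.

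Iron, efflux and mobile element lists had members in both directions; with an equal total per library 4, 2 and 2 genes were higher against 19, 23 and 22 lower, and with an equal upper quartile 9, 3 and 6 against 14, 20 and 17. Of 24 iron genes, 12 rose and 12 fell (camera adjusted p = 0.947; median −0.03, mean 0.33). Ferritin FORC47_RS26160 rose by 2.90, a siderophore-binding protein gene (FORC47_RS26350) by 2.56, and entC, which here names a cell wall-binding protein, by 3.86. Of 25 efflux genes, 8 rose and 14 fell (adjusted p = 0.453). RND family genes FORC47_RS28065 and FORC47_RS04260 rose by 2.34 and 2.25, and an HlyD family gene (FORC47_RS27080) fell by 1.18. The gene ycaC, listed there by a product pattern and naming a hydrolase, fell by 1.65. Of 24 prophage, transposase and integrase genes, 8 rose and 12 fell (adjusted p = 0.719). Recombinase FORC47_RS07570 rose by 3.32 and the integrase FORC47_RS19125 by 1.41, the latter at −0.53 with an equal total per library, while transposase FORC47_RS28740 fell by 1.52. spoIIIJ, a membrane protein insertase matched by its product name, rose by 2.43. The porin list held an OmpA family gene (FORC47_RS08445) and an aquaporin gene (FORC47_RS23195), which rose by 1.60 and 1.07 but stood at −0.35 and −0.87 with an equal total per library. The type VI secretion list held only hcp, here a hydroxylamine reductase, at −0.12 (limma adjusted p = 0.0823). The lists for the sodium-translocating NADH:quinone reductase and ribosomal proteins had 0 members. Counts were the same when adjusted over each list alone, and median control levels of the iron, efflux and prophage lists were 566, 457 and 191 normalized counts.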

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

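All settings were chosen before the data were examined, except pseudocount 4 and limma-voom on recovered reads, which were chosen after. The planned edgeR and DESeq2 fits were not run. The number of changed genes stayed between 4243 and 4523 over the other settings, apart from the fold threshold: 2926 genes changed at least 2-fold, 1356 of them lower, because that threshold adds a criterion. Without each library in turn, 4243 to 4418 genes changed, 2137 to 2213 higher and 2106 to 2213 lower; a lone library is then assumed to vary like the other group. Limma-voom called 4404 genes and pseudocount 4 called 4408. With an equal total per library, 830 genes were higher and 3693 lower, since that scaling moved the median log2 fold change by −1.93. It reversed putP FORC47_RS06355 (−0.99), FORC47_RS20515 (−0.23), FORC47_RS06850 (−0.26), FORC47_RS21175 (−0.28), FORC47_RS28290 (−0.999), FORC47_RS08445 (−0.35), FORC47_RS23195 (−0.87), FORC47_RS08630 (−0.16), FORC47_RS08645 (−0.79), hisC (−0.58), cysE (−0.15), phaC (−0.22) and FORC47_RS19125 (−0.53). With an equal upper quartile, putP FORC47_RS06355 (−0.0258) and FORC47_RS28290 (−0.0363) reversed. Over named genes and settings, 2524 results kept direction and call, 1 weakened (FORC47_RS23195, 0.09 with an equal upper quartile), 4 became stronger and 15 reversed. The 4 were all hcp FORC47_RS17530, at −0.39 with TMM, −1.10 with an equal upper quartile, −2.06 with an equal total and −0.18 without salt replicate 1. Camera called 12 lists, and 12 to 14 under other gene-level settings and by symbol alone (14 without each library in turn). With an estimated correlation it called 0, against 12 with the preset correlation, and fry called 29. Fry gave the opposite direction for potassium uptake (fry adjusted p = 0.00337), proline and glutamate synthesis (0.00473) and iron uptake (0.000477). Fry tests a list against no change and camera against the other genes. The mean log2 fold changes of these lists were above 0, at 0.21, 0.24 and 0.33. The type IV pilus list was lost without either salt library, with the replicate block and with equal totals or upper quartiles, and had too few members by symbol; the peptidoglycan list was lost with equal totals. The cause was not tested. With the replicate number as a block, 4428 genes changed (2215 higher, 2213 lower) and 14 lists passed. Same-numbered libraries share only a number: their deviations correlated at 0.0346. In each salt library 31 genes had 0 reads, against 0 genes in the controls.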

Other observations

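All tests in this part were chosen after the gene names and values were seen. Of 180 tested genes of sporulation and spore germination, 37 rose and 135 fell in salt (median log2 fold change −1.39, camera adjusted p = 9.94e-07, adjusted p = 0.238 with an estimated correlation), and the counts were 32 and 143 with TMM, 23 and 154 with an equal upper quartile and 8 and 166 with an equal total per library. Among the members that rose were spo0A, the master regulator of entry into sporulation, by 2.40 and spo0F of its phosphorelay by 2.42. The sigma factor gene sigG fell by 2.97, the cortex-lytic enzyme gene sleB by 3.16 and a collagen-like exosporium protein gene (FORC47_RS24375) by 3.24. The list's median control level was 266 normalized counts, against 332 over all tested genes. Its median salt level was 99.7. Over all genes, deciles of salt level with medians of 66.2 and 113 in salt had control medians of 171 and 239. Genes of similar salt level were thus lower in salt in general, though ranking by salt level by itself pulls that way. The fall is therefore not shown to be particular to sporulation genes. All 3 genes of the sigma B operon, which governs general stress in spore-forming bacteria, rose (sigB 3.37, rsbV 3.22, rsbW 2.64; camera adjusted p = 0.0478, adjusted p = 0.469 with an estimated correlation).

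All 7 genes of pyruvate and branched-chain keto acid dehydrogenase and linked butyrate steps rose (median 4.59, camera adjusted p = 0.00217, adjusted p = 0.344 with an estimated correlation), as did all 11 genes of RNA polymerase and its cofactors (median 3.58, camera adjusted p = 0.000242, adjusted p = 0.469 with an estimated correlation), both under each scaling. Of 11 enterotoxin and secreted virulence genes, 10 rose and 1 fell (median 1.96, camera adjusted p = 0.0166, adjusted p = 0.469 with an estimated correlation), and with an equal total per library 4 were higher and 5 lower. The 3 arginine deiminase pathway genes rose (camera adjusted p = 0.140), and with an equal total per library 1 was higher and 1 lower, with a median of −0.05. Of these, arcA was among the 10 highest protein-coding genes of the controls at 6625 normalized counts, against 65141 in salt. Natural competence (3 higher, 12 lower, adjusted p = 0.0749) and petrobactin and bacillibactin synthesis (2 higher, 2 lower, adjusted p = 0.669) did not pass. The largest fold in the latter list, 3.86, is that of entC, which here names a cell wall-binding protein. Genes below the median salt level with tag numbers under 2000 or between 26000 and 28000 were compared with those between 12000 and 15000. The 178 genes of the former ranges stood 1.68-fold (95% bootstrap interval 1.29 to 1.95) above the 324 of the latter in the controls. In salt they stood 1.41-fold (1.14 to 1.72) above them, an interval that overlaps that of the controls. Tags above 28000 were left out, so these ratios do not describe the end of the series. Over all genes, control medians of successive tag ranges there lay between 71.1 and 578 normalized counts, against 183 to 226 between 12000 and 15000.

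The controls spread less between genes than the salt libraries, with an SD of log2 values of at most 1.45 against 2.54. Depth does not account for it, since the salt libraries thinned to 4437046 reads still had an SD of at least 2.54. A candidate explanation is even coverage of the genome in the controls, as DNA in the libraries would give: control level followed namesake length with a Spearman correlation of 0.772 and salt level with 0.361, a difference of 0.41 (95% bootstrap interval 0.336 to 0.487). Lengths covered only 7.17% of genes and came from another species, so the length test is void over the table and leaves this open. A change of transcription between the cultures cannot be told apart from it for the same reason, although salt level alone predicted control level in genes left out with a correlation of 0.678.

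If the controls held such a background, genes lower in salt might be genes with little RNA in either group. The folds of genes higher in salt are open to the same question. From the lowest to the highest decile of salt level, medians rose from 23.4 to 7125 normalized counts in salt (305-fold). Control medians of the same deciles rose from 76.2 to 888 (11.6-fold), though ranking by salt level by itself widens the salt range. A fit of control level as 3.85% of the salt level plus 423 normalized counts per kilobase of namesake predicted genes left out with a correlation of 0.921. It covers 270 of the genes called higher and 55 of those called lower, or 2.50% of the latter. This test is therefore void for the table and the explanation stays open. The genes most above the fit in the controls were pflA and pflB of formate production, by 1.99 and 1.77 on the log2 scale.

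Gene names do not match the labelled organism: the table holds 0 nqr symbols, against 4 in V. natriegens. It also holds 41 symbols that begin with spo. In V. natriegens 0 symbols begin with spo0 or spoI, a narrower pattern, so these spo counts are not like for like. Reads of a distant species aligned to this reference are argued against by 4572 of 4759 genes with at least 10 reads in all 4 libraries. Libraries from a spore-forming bacterium related to the reference remain a candidate explanation, and for the assigned reads the 4572 genes go with it. The sporulation list adds nothing to this: 164 of 181 sporulation and germination genes (90.6%) passed that mark, but so did 96.1% of all genes. The test on that list is therefore void. Reads that did not align to this reference are not analysed here, so a mixed culture stays untested. No biological explanation was tested for this pattern.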
